A study of Homo sapiens with 8 samples.

How the data were processed

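RNA sequencing libraries were made from HEK293T cells, a human embryonic kidney line. Per the labels' protocols, the cells received 2 µg per well of plasmids encoding the RNA-targeting nuclease CasRx and a guide RNA 12 h after passage. Fluorescent cells were collected 2 days later by their EGFP and mCherry signals, and 1 µg of total RNA extracted with Trizol entered a TruSeq RNA library kit. The labels assign 2 libraries to a LacZ guide, which served as the control, 3 to RPL4 guide 1 and 3 to RPL4 guide 2. A further control library was discarded by the authors for quality, per the labels, and was not analysed here.

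The submitters' processing notes name FastQC, Trim Galore, HISAT2, HTSeq and the GRCh38 build without versions. The annotation release, the strand setting of the counting and the program behind the FPKM values were not given in the sources used here. The deposited tables held 60675 genes by Ensembl identifier, of which 57055 occur in GENCODE release 29 (GRCh38), the source of the gene types, coordinates and exon lengths used below. Exon length is that of all annotated exons of a gene joined, which can exceed the length of its mRNA. A symbol stood on more than 1 line for 264 symbols, so genes were followed by identifier. The authors deposited a table of counts, whole numbers of reads per gene with no normalization, and a table of FPKM, reads scaled by a divisor per gene and by library depth, for the same 8 libraries.

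The tables were compared with each other before any test. In a library, each FPKM value is a whole number of reads divided by the library's depth and by a divisor per gene, so the spacing of the values gives the reads back. All values tested came out whole within 0.1 read in each library. In 7 libraries the recovered reads equalled the deposited counts for each gene with a divisor, 96.0% to 97.57% of the genes with reads. In control replicate 2 they did not: the FPKM column corresponded to a depth of 11867029 reads and the deposited count column summed to 13553395, 2.73% of genes had equal values, and the log2 values of the columns had a Pearson correlation of 0.789 across genes. The recovered reads of control replicate 2 (11866262, with 580 genes lacking a divisor and set to 0) were therefore used beside the deposited counts of the other 7 libraries. This departs from the plan to use every count column as deposited, and it was decided after the columns had been compared and before any test. Nothing in the sources shows which column holds the library named, so the main results are given also with the deposited counts of control replicate 2 and without that library. The divisors of the FPKM table correlated only moderately with exon length (Spearman rho 0.429 over 15873 genes, largest divisor 9466), so FPKM values were compared within genes, never between them.

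Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups (16594 genes), libraries were scaled by TMM, and all 8 libraries entered a single quasi-likelihood fit (glmQLFit, robust) without covariates. Guide 1 and guide 2 were each tested against the control, and guide 2 against guide 1, by glmQLFTest. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The values after ± are standard deviations between libraries of CPM on TMM-scaled library sizes, and SE is the standard error of a log2 fold change. No label says that the libraries of a group came from separate cultures.

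The comparisons, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named RPL4. For each guide against the control it took the 10 largest rises and 10 largest falls among genes past the threshold whose 3 guide libraries all lay beyond both control libraries and whose mean CPM reached 5 in either group, and for guide 2 against guide 1 the 5 largest in each direction. In each gene list it took the 3 members with the smallest p. List members named because 5 or fewer moved in their direction, and the examples RPL29, NDUFA11, SNHG9, E2F1 and HIST1H4J, were chosen after their values were seen. The 18 gene lists were written from textbook knowledge: ribosomal proteins other than RPL4, mitochondrially encoded mRNAs, nuclear-encoded respiratory chain subunits, ribosome biogenesis factors, p53 targets, ATF4 targets of the integrated stress response, immediate early and ribotoxic stress genes, interferon-stimulated genes, NF-kB targets, the heat shock response, the ER unfolded protein response, replication-dependent histones, S phase genes, G2 and mitosis genes, snoRNA host genes, cholesterol synthesis, glycolysis, and markers of other cell types. NOP53, SNHG29, SNHG30, SNHG32 and CYTOR matched no symbol in the tables. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and p-values were adjusted over 36 tests (18 lists, both guides against the control). Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way, and its mixed form whether they change in either direction; neither compares a list with other genes.

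The test was tried on simulated counts drawn from the means, spread and library sizes of these libraries, with 200 of 16594 genes changed in each of 2 simulations. For guide 1 against the control it called 24.6% of genes changed 1.5-fold, 61.9% of those changed 2-fold and 84.8% of those changed 4-fold, and 16 of 32788 unchanged genes. For guide 2 against the control the shares were 23.9%, 67.2% and 88.6%, with 23 unchanged genes called, and for guide 2 against guide 1 they were 27.6%, 61.2% and 84.8%, with 12. Because both guides were compared with the same control libraries, 20 simulations of unchanged groups were set against them. These gave the overlap and correlation that shared controls produce when neither guide changes any gene.

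The alternatives were DESeq2 size factors, library size alone and TMM without mitochondrial genes in edgeR; the DESeq2 1.42.0 Wald test; limma-voom; limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, and on log2(FPKM + 1) without that filter; no count filter; a mean CPM of at least 5; fits of the groups compared alone; a replicate block by either numbering of the labels; a 2-fold minimum change; and leaving out each library in turn. Where this left a single control library, its spread was taken from the other groups. The use of the deposited counts of control replicate 2 was added after the data were seen. To set gene lists against genes of like length, the median of each was ranked among 10000 random lists drawn from the 50 nuclear protein-coding genes nearest to each member in exon length and expression; this comparison was chosen after the fold changes, and for lists other than the mitochondrial one after the trend with exon length, had been seen. Genes that share sequence were found from words of 31 bases shared with the exons of other genes, and over 50% of words shared was treated as uncertain. Because the strand setting is not given, reads of an antisense gene and of the gene it overlaps cannot be told apart. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 computed the remaining values, and matplotlib 3.10.9 drew the figures.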

Results

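The series asks whether CasRx, a nuclease that cuts RNA under the direction of a guide RNA, affects transcripts other than its target when the target is an endogenous mRNA. The target was RPL4, which encodes a protein of the large ribosomal subunit. HEK293T cells received CasRx with a LacZ guide (control, 2 libraries), with RPL4 guide 1 (3 libraries) or with RPL4 guide 2 (3 libraries). The libraries held 11064589 and 11866262 reads in the control (the latter recovered from the FPKM values), 13898522, 11872876 and 14457832 with guide 1, and 11998157, 11214149 and 10957278 with guide 2. Mitochondrially encoded transcripts took 16.4% and 16.4% of the reads in the control, 19.3%, 20.7% and 25.2% with guide 1, and 17.4%, 17.9% and 16.8% with guide 2. The read-weighted median exon length was 4506 and 4491 bases in the control, 4245, 4001 and 3540 bases with guide 1, and 4345, 4315 and 4381 bases with guide 2. TMM factors lay between 0.996 and 1.04 except in guide 1 replicate 3 (0.867). The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

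RPL4 (ENSG00000174444; GRCh38 chromosome 15, 66498015 to 66524532, minus strand) was lower in each of the 6 RPL4 guide libraries than in either control library. It stood at 2119 and 2150 CPM in the control libraries. With guide 1 it stood at 607, 682 and 858 CPM, which is 28.4%, 32.0% and 40.2% of the control mean, and with guide 2 at 1131, 1148 and 1181 CPM, which is 53%, 53.8% and 55.3%. It fell by 1.58 on the log2 scale with guide 1 (SE 0.133, adjusted p = 2.26e-05) and by 0.89 with guide 2 (SE 0.133, adjusted p = 0.0428), and it was higher with guide 2 than with guide 1 by 0.69 (SE 0.121, adjusted p = 0.00244). Of the 31-base words of RPL4, 21.5% also occur in other genes, mostly its pseudogenes. The guide 1 call held in every alternative, with the deposited counts of control replicate 2 at a log2 fold change of -2.79 (adjusted p = 0.0443). The guide 2 call did not hold without control replicate 1 (adjusted p = 0.713), control replicate 2 (0.455), guide 1 replicate 2 (0.155), or guide 2 replicate 1 (0.466), 2 (0.276) or 3 (0.287), nor with the deposited counts of control replicate 2 (log2 fold change -2.09, adjusted p = 0.330). It also failed with limma-voom (0.132), unfiltered log2(FPKM + 1) (0.0528), a mean CPM of at least 5 (0.0630) and the replicate block by title (0.133). The guide 2 call held with guide 2 and control fitted alone (adjusted p = 3.06e-09), without a filter (7.74e-12) and with DESeq2 (6.04e-07). Without guide 1 replicate 1 (0.00235) or 3 (1.84e-08) it held too. Leaving out any 1 library, the guide 2 log2 fold change of RPL4 stayed between -0.91 and -0.87.

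With guide 1 all 15 genes of the list of replication-dependent histones that were tested rose, and genes of mitosis and glycolysis were among those that fell. HIST1H4E, which encodes histone H4, rose 21.1-fold, from 4.77 ± 0.876 CPM in the control (n = 2) to 101 ± 9.32 (n = 3). PLK1, the kinase that drives mitotic entry, fell from 82.3 ± 4.04 to 35.9 ± 3.81 CPM, and HK1, the hexokinase that starts glycolysis, from 137 ± 3.06 to 48.6 ± 3.01. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 5437 of 16594 genes passed, 2872 up (52.8%) and 2565 down, of which 1123 and 356 changed at least 2-fold. Rises and falls are relative to the other reads of a library, and no measure of RNA per cell entered the scaling. A change shared by most genes would therefore be scaled away. The split depended on the scaling, and with library size alone 41.9% of the passing genes rose. With limma on log2(FPKM + 1), which also changes the test and the genes tested, 39.1% did. The median of all genes tested was 0.02 on the log2 scale with TMM and -0.10 and -0.12 on the log2(FPKM + 1) and log2(FPKM + 0.1) scales. Without control replicate 1 the count was 2636, without control replicate 2 it was 2692, and with the deposited counts of control replicate 2 it was 187 (4212 at an unadjusted p under 0.05). With those deposited counts, 15 of the 73 named genes that passed with guide 1 passed in the same direction, among them RPL4, HIST1H4E, HIST2H2BE, HIST1H4H, POLA2, BUB1, CCNG1, DNAJB6 and PDIA4; 51 no longer passed and 7 changed sign.

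The largest rises among genes at 5 CPM or more were mostly of noncoding genes. HIST1H4E (log2 fold change 4.40, SE 0.247, adjusted p = 2.24e-06) and HIST3H2A, an H2A histone (3.54, SE 0.285, adjusted p = 1.67e-05), were the protein-coding genes among the 10. The antisense genes RP11-370I10.12 (log2 fold change 3.79), LINC01311 (3.48) and CTD-2287O16.5 (3.47, on the strand opposite COMMD10) rose, as did the long intergenic noncoding RNAs RP4-760C5.3 (3.70), RP11-707G18.1 (3.58), RP11-321F8.4 (3.34) and RP11-277B15.3 (3.32) and the unclassified transcript RP11-477I4.4 (3.59), with adjusted p between 6.20e-06 and 0.00153. The largest falls included the receptor tyrosine kinase gene FLT3 (log2 fold change -2.06, SE 0.563, adjusted p = 0.0160), whose control level was uneven (5.57 ± 3.50 CPM) and whose call was lost without control replicate 1 or any guide 1 library. ZHX2, a transcriptional repressor, fell by 1.74 (SE 0.177, adjusted p = 5.40e-05), SYPL2 by 1.70, the glypican gene GPC6 by 1.64, SDK1 by 1.57 and the collagen gene COL14A1 by 1.56. IGFBP5, an insulin-like growth factor binding protein, fell from 43.0 ± 2.61 to 14.4 ± 2.89 CPM (log2 fold change -1.57, SE 0.163, adjusted p = 5.81e-05). CTD-2562J17.6 fell by 1.68, and a processed pseudogene, AC090498.1, whose sequence is fully shared with other genes and whose level is therefore uncertain, fell by 1.78. RPL4 itself was among the 10.

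All 15 replication-dependent histone genes tested rose, over all genes and adjusted over the list alone, with a median log2 fold change of 2.85 (camera adjusted p = 2.54e-14; adjusted p = 0.0230 with an estimated correlation). HIST2H2BE, an H2B gene, rose 8.46-fold (SE 0.148 log2, adjusted p = 6.91e-07) and HIST1H4H 6.92-fold. HIST1H4J had a log2 fold change of 4.12, but it missed the naming rule's minimum level or its separation of libraries. These mRNAs normally end in a stem-loop and not in a poly(A) tail. Counts per gene do not tell forms with a tail from forms without one, and how the kit selected RNA is not stated here. The 19 snoRNA host genes, whose introns carry small nucleolar RNAs and several of whose mRNAs also carry 5' terminal oligopyrimidine tracts, had 14 members that rose and none that fell (16 and 0 adjusted over the list alone; median 0.90, camera adjusted p = 1.09e-06; adjusted p = 0.593 with an estimated correlation). SNHG15 rose from 126 ± 8.05 to 374 ± 46.2 CPM, SNHG17 by 1.49 and SNHG1 by 0.90 on the log2 scale, and SNHG9 by 2.63. With the deposited counts of control replicate 2 the median of this list was -0.60 and its adjusted p 0.960.

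Cell cycle genes split by phase. Of 50 G2 and mitosis genes 34 fell and UBE2C alone rose (35 and 1 adjusted over the list alone; median -0.50, camera adjusted p = 6.05e-12; adjusted p = 0.341 with an estimated correlation). PLK1 fell by 1.20 (SE 0.116, adjusted p = 4.15e-05), the spindle factor TPX2 by 1.15 and the checkpoint kinase gene BUB1 by 1.10. Of 47 S phase genes 17 rose, while POLA1 and HELLS fell (17 and 2 adjusted over the list alone; median 0.24, camera adjusted p = 6.59e-04; adjusted p = 0.0754 with an estimated correlation; adjusted p = 0.143 with the deposited counts of control replicate 2). POLA2, a subunit of the primase complex, rose by 1.26, the clamp loader gene RFC5 by 1.21, E2F1, a transcription factor of the G1 to S transition, by 1.51, and TIPIN, a replication fork protein, by 0.92, the last with the opposite sign under the deposited counts of control replicate 2 (-0.15).

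In glycolysis 10 of 20 genes fell and PGAM1 rose (11 and 1 adjusted over the list alone; median -0.39, camera adjusted p = 0.00128; adjusted p = 0.447 with an estimated correlation). HK1 fell by 1.49 (SE 0.0984, adjusted p = 6.20e-06), the enolase gene ENO1 by 0.85 and the lactate transporter gene SLC16A1 by 0.78. Of 33 ATF4 targets, the genes of amino acid supply induced in the integrated stress response, 18 fell and 5 rose (19 and 5 adjusted over the list alone; median -0.37, camera adjusted p = 0.00667; adjusted p = 0.901 with an estimated correlation). PSAT1 of serine synthesis fell by 0.89 and the amino acid transporter gene SLC7A1 by 0.82, while SLC3A2, the heavy chain of amino acid transporters, rose by 0.86 and ATF3 by 0.57, as did DDIT3, PPP1R15A and STC2.

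In the respiratory chain and the ribosome more genes rose than fell. Of 74 nuclear-encoded respiratory chain genes 36 rose and 6 fell (39 and 6 adjusted over the list alone; median 0.42, camera adjusted p = 3.34e-05; adjusted p = 0.901 with an estimated correlation and 0.168 with fry). The complex I gene NDUFA3 rose by 2.02 on the log2 scale, ATP5H of ATP synthase 2.83-fold, cytochrome c (CYCS) by 1.09 on the log2 scale and NDUFA11 by 2.72. Of the 79 ribosomal protein genes other than RPL4, 27 rose and 11 fell (29 and 11 adjusted over the list alone; median 0.31, camera adjusted p = 0.0146; adjusted p = 0.937 with an estimated correlation and 0.689 with fry). RPL36A rose by 1.00 and RPL29 by 2.06, while RPS12 (35.5% of words shared with other genes) fell by 1.36 and RPL21 (31.4%) by 1.01. Without guide 1 replicate 3 the ribosomal list no longer passed (median 0.13, adjusted p = 0.588), and with the deposited counts of control replicate 2 both medians turned, to -1.60 for ribosomal proteins and -1.01 for the respiratory chain, with ATP5H at -0.24 and CYCS at -0.20. A replicate block by description also ended the call of the ribosomal list. The genes of both lists are short, and the read-weighted exon length was lowest in the guide 1 libraries.

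Of the 13 mitochondrially encoded mRNAs, MT-ND1 (0.82), MT-ND4 (0.57), MT-ND2 (0.56), MT-ND4L (0.48) and MT-CO1 (0.48) rose and MT-ATP8 fell by 1.04 (6 and 1 adjusted over the list alone; median 0.48, camera adjusted p = 0.0479; adjusted p = 0.901 with an estimated correlation). The log2 fold changes of MT-ND3, MT-ND5, MT-ND6, MT-CO2, MT-CO3, MT-ATP6 and MT-CYB did not pass. With a replicate block by description the list was not called. The list was lost without control replicate 1 (adjusted p = 0.0725), control replicate 2 (0.111) or guide 2 replicate 1 (0.0633), 2 (0.0675) or 3 (0.0700), and with the deposited counts of control replicate 2 (0.129). MT-CO1, MT-CO2, MT-ND2 and MT-ATP6 share 66.7%, 50.5%, 56.9% and 63.7% of their words with other genes, so their levels are uncertain.

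The other stress and signalling lists did not pass as lists, with members in both directions. Among 37 immediate early and ribotoxic stress genes 9 rose, with the AP-1 gene FOSL1 at 1.24 and GADD45A at 0.61 (-0.16 with the deposited counts of control replicate 2), and KLF6 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0671). That adjusted p was 0.0408 and 0.217 without control replicate 1 and 2, 0.00623, 0.0400 and 0.588 without guide 1 replicate 1, 2 and 3, the last with a median of 0.13 against 0.31, and 0.0167 with those deposited counts. Of 29 p53 targets BAX, GADD45A, PHLDA3 and AEN rose and CCNG1 (-1.02), TIGAR (-0.73), RRM2B (-0.70), XPC and CDKN1A fell (5 and 5 adjusted over the list alone; adjusted p = 0.546). Of 28 interferon-stimulated genes IFITM2 rose by 0.98 (-0.84 with the deposited counts of control replicate 2) and members including HERC5 (-0.59), BST2 and SAMD9 fell (1 and 3 adjusted over the list alone; adjusted p = 0.401, and 0.0286 with those deposited counts). Of 20 NF-kB targets the cytokine gene IL32 (1.34), NFKBIB (0.93) and NFKB2 rose and NFKB1 (-1.33) and CD83 fell (2 and 2 adjusted over the list alone; adjusted p = 0.745). Of 25 heat shock genes MRPL18 (0.94; -0.57 with those deposited counts), HSPB1 and HSPE1 rose and the chaperone genes DNAJB6 (-1.05), HSPA8 (-0.81), HSP90AA1, CHORDC1 and HSP90AB1 fell (3 and 5 adjusted over the list alone; adjusted p = 0.991).

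Of 28 genes of the ER unfolded protein response 6 rose and 9 fell, including the disulfide isomerase genes PDIA4 (-0.98) and PDIA6 (-0.78) and the chaperone gene HYOU1 (-1.05; 6 and 10 adjusted over the list alone, camera adjusted p = 0.401, and 0.0167 with the deposited counts of control replicate 2). Fry, which tests movement one way on balance, gave this list an adjusted p of 0.0263 downward, and its mixed form, which tests change in either direction, 1.34e-05. Of 24 cholesterol synthesis genes EBP (0.89; -0.42 with the deposited counts of control replicate 2) and NSDHL rose and members including SREBF2 (-0.46), HSD17B7, FDFT1 and FDPS fell (1 and 5 adjusted over the list alone; adjusted p = 0.401, and 0.0167 with those counts). Of 47 ribosome biogenesis genes 14 rose, with BYSL at 1.27, and 6 fell, with NOP14 at -0.78 and RRP1B at -0.55 (14 and 6 adjusted over the list alone; adjusted p = 0.488). The medians of the ribosome biogenesis and heat shock lists, 0.09 and 0.07, turned to -0.01 and -0.04 with library size alone. None of the 7 markers of other cell types tested passed (adjusted p = 0.983; COL1A1 0.01, EPCAM 0.55), and MYH11, at -1.87, had an SE of 1.08. The median of that list was above 0 and its mean, -0.22, and camera's direction were below.

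With guide 2, RPL4 was lower and histone mRNAs were again higher, with few single genes past the threshold. HIST1H4E rose 3.39-fold, from 4.77 ± 0.876 (n = 2) to 16.1 ± 4.68 CPM (n = 3), HIST2H2BE 2.38-fold, from 16.6 ± 0.419 to 39.4 ± 2.24, and HIST1H4H 2.34-fold, from 4.35 to 10.2. MADCAM1, an adhesion molecule of endothelium, rose 4.19-fold (1.27 ± 0.166 to 5.35 ± 0.374 CPM), TMEM116, a transmembrane protein, 1.84-fold (19.3 to 35.5 ± 3.53) and the antisense gene RP11-370I10.12 3.57-fold, though below 5 CPM in both groups. In edgeR's test 7 genes passed, these 6 up and RPL4 down, with adjusted p between 0.0170 (HIST2H2BE) and 0.0428 (RPL4), and 1338 genes had an unadjusted p under 0.05. DESeq2 called 34 genes and limma-voom 0 (1226 at an unadjusted p under 0.05). The edgeR count was 0 without control replicate 1 (733 at an unadjusted p under 0.05), control replicate 2 (788), guide 1 replicate 2 (1083) or guide 2 replicate 3 (1052), and with the deposited counts of control replicate 2 (2415). It was 1 without guide 2 replicate 1, 20 without guide 1 replicate 1 and 206 without guide 1 replicate 3. With guide 2 and control fitted alone the edgeR count was 493, and without a filter 74.

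Of the 15 histone genes 3 rose with guide 2 (10 and 0 adjusted over the list alone; median 0.89, camera adjusted p = 1.69e-15; adjusted p = 0.0230 with an estimated correlation; 0.0781 with the deposited counts of control replicate 2). No member of any other list passed over all genes. The G2 and mitosis list was lower than other genes (median -0.13, adjusted p = 9.05e-06; adjusted p = 0.593 with an estimated correlation), with PLK1 at -0.23. The snoRNA host list was higher (median 0.24, adjusted p = 5.56e-05; adjusted p = 0.708 with an estimated correlation), with SNHG15 at 0.45 and 1 gene up adjusted over the list alone. Respiratory chain genes (median 0.15, adjusted p = 6.91e-05; adjusted p = 0.901 with an estimated correlation) and ribosomal proteins (median 0.15, adjusted p = 1.61e-04; adjusted p = 0.936 with an estimated correlation) were also higher as lists. Both of these calls were lost with a replicate block by description. With the deposited counts of control replicate 2 the snoRNA host, respiratory chain and ribosomal medians were -1.18, -1.47 and -1.85. Interferon-stimulated genes were lower as a list (median -0.11, adjusted p = 0.0487; adjusted p = 0.341 with an estimated correlation), a call lost with DESeq2 size factors (0.0521) and without control replicate 1 or 2, guide 1 replicate 1 or 3, or guide 2 replicate 1 or 2 (0.0657 to 0.115). In glycolysis (median 0.02, adjusted p = 0.745) HK1 alone passed adjusted over the list alone, with a log2 fold change of -0.46 and an adjusted p of 0.235 over all genes.

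The remaining lists had no call with guide 2. The adjusted p was 0.114 for immediate early genes. It was 0.0435 and 0.549 without control replicate 1 and 2, 8.97e-04, 0.353 and 0.741 without guide 2 replicate 1, 2 and 3, and 0.0495 with the deposited counts of control replicate 2. The adjusted p was 0.991 for S phase, p53 and ER unfolded protein response genes, 0.752 for ATF4 targets, 0.745 for mitochondrial mRNAs, 0.401 for ribosome biogenesis (0.0495 with those deposited counts, median -0.24), 0.546 for NF-kB targets and other cell type markers, 0.947 for heat shock and 0.825 for cholesterol synthesis. In glycolysis, ATF4, S phase, p53, ER and cholesterol lists the median differed in sign from the mean or from camera's direction, with medians between -0.05 and 0.02.

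The guides shared 7 calls, 6 up and 1 down, and no gene passed in opposite directions. The shared count was 421 with the groups compared alone, 198 without guide 1 replicate 3, 0 without guide 1 replicate 2 and 0 with limma-voom. Independent lists of the sizes in the main fit would share 1.04 genes up and 0.155 down. Unchanged groups simulated against the same control libraries shared 0.05 on average (0 to 1 in 20 simulations). Those groups had only 0.75 and 0.4 calls on average, against 5437 and 7 here, so they could share few. They cannot tell how many calls shared controls would add to lists as long as these. Each of the 7 genes moved further with guide 1, with MADCAM1 up 8.34-fold and TMEM116 4.17-fold there. Across all genes the log2 fold changes of the guides had a Pearson correlation of 0.687, against 0.624 (0.595 to 0.666) in simulations of unchanged groups that share the control. Their covariance was 0.202 against a simulated 0.0913, a difference of 0.111. With a separate control library for each guide the correlations were 0.333 and 0.392 and the covariances 0.0953 and 0.112. There the guides share no control library, and the covariances stood near the difference of 0.111. This argues against the noise of single shared control libraries as the source of that difference. A deviation common to both control libraries would remain in these values, and genes are not independent replicates.

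Tested directly, guide 2 had lower levels of replication-dependent histone mRNAs than guide 1, and higher levels of many mitotic genes. All 15 histone genes were lower (15 adjusted over the list alone; median -1.63), with HIST1H4E at 16.1 ± 4.68 against 101 ± 9.32 CPM (log2 fold change -2.64, SE 0.182, adjusted p = 3.30e-05, n = 3 each), HIST3H2A at -2.39 and HIST2H2BE at -1.83. In the G2 and mitosis list 24 genes were higher and none lower (31 and 0 adjusted over the list alone), with PLK1 at 0.96. HK1 was higher by 1.03. In total 3467 genes passed in edgeR's test, 1577 higher (45.5%) and 1890 lower with guide 2, and 541 differed at least 2-fold; with library size alone 58.0% were higher and with limma on log2(FPKM + 1) 61.0%. The count was 2000 without guide 1 replicate 2, and 2061, 1891 and 2083 without guide 2 replicate 1, 2 and 3. With the deposited counts of control replicate 2 in the shared fit, where its spread enters, it was 0 (1878 at an unadjusted p under 0.05), while DESeq2 and limma-voom on the recovered reads gave 3440 and 3372.

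Among the genes with the largest differences, the pseudogene AC090498.1 (1.41, fully shared with other genes), COL14A1 (1.39, SE 0.213, adjusted p = 0.00117) and GPC6 (1.31) were higher with guide 2, as were IGFBP5 (1.21) and RPL4. NOMO3 (1.35; 68.4% of words shared with other genes, mostly NOMO1) was too, a call lost without guide 1 replicate 3 or guide 2 replicate 3, and so was the pseudogene RPL41P5 (1.34, fully shared). LINC01311 (-2.18), the antisense gene ENSG00000272631 (-2.15) and RP4-798A10.7 (-2.10; 75.8% of words shared) were lower. SNHG15 was lower by 1.12, and 12 snoRNA host genes were lower and 0 higher (13 and 0 adjusted over the list alone). Of S phase genes 15 were lower and 0 higher (17 and 0), including RFC5 at -1.11. Of glycolysis genes 11 were higher and 1 lower (12 and 1), and of ATF4 targets 12 and 2 (19 and 3), with SLC7A1 at 0.75 and PSAT1 at 0.69. Respiratory chain genes were lower in 29 and higher in 7 cases (30 and 7), ribosomal proteins in 14 and 9 (15 and 9), and mitochondrial mRNAs in 4 and 0 (6 and 1).

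Fold changes followed exon length with both guides. Among protein-coding genes the median log2 fold change with guide 1 was 0.81 for the 102 genes with exons of up to 1000 bases, 0.42 from 1000 to 2000 (888 genes), 0.13 from 2000 to 4000 (3561), -0.07 from 4000 to 8000 (5725) and -0.25 above 8000 (2994). With guide 2 the medians were 0.23, 0.14, 0.05, -0.02 and -0.10. Spearman's rho across 16496 genes was -0.368 with guide 1 and -0.317 with guide 2, against -0.0323 to 0.0126 and -0.0177 to 0.0113 in simulations of unchanged groups. The simulated groups carry no length shift between libraries, so a rho near 0 was built in and the range is no measure of such shifts. Control replicate 2 against control replicate 1 gave -0.0659, outside that range. Set against random lists of genes matched on exon length and expression, the guide 1 median stood above all of 10000 lists for histones and snoRNA hosts (percentile 100) and below all for G2 and mitosis genes and ATF4 targets (percentile 0). It stood at percentile 99.84 for S phase genes, 99.99 for ribosomal proteins, 99.9 for the respiratory chain and 0.20 for glycolysis. The random lists hold protein-coding genes, while SNHG15, SNHG17 and SNHG1 are noncoding. With guide 1 the median was 0.61 for intergenic noncoding genes and 0.33 for processed transcripts, against -0.04 for protein-coding genes. The rank of snoRNA hosts can therefore reflect gene type. Random lists do not carry the correlation between members, and of these lists only the histones passed with an estimated correlation (adjusted p = 0.0230, against 0.0754 to 0.937). Exon length joins all annotated exons of a gene, with a median of 3002 bases for ribosomal proteins, so matched genes may differ in mRNA length. These ranks therefore cannot show a shift beyond that of mRNA length.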

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

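The tests of the count column of control replicate 2, of a length shift that needs no guide and of separate handling of the groups were chosen only after the results were seen; the tests of length, of expression level and of other splits of the guide libraries were chosen before.

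Guide 1 and guide 2 differed from each other in the direct test. The 3467 genes past the threshold, the RPL4 difference of 0.69 on the log2 scale and the median of -1.63 over the 15 histone genes each marked a difference between the libraries of the guides. The 6 guide libraries can be split into 3 and 3 in 10 ways, so the share of splits as large as the real one cannot be under 0.1; 1 split, the real one, gave 3467 genes, and the highest other gave 0.

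The deposited count column of control replicate 2 and its FPKM column describe different sets of reads. If the same reads had been counted with other settings, most protein-coding genes that overlap no other gene would share a ratio, but 9.58% of 4957 such genes lay within 10% of the median ratio of 0.614 (middle 50% from 0.369 to 1.14), which argues against it. A guide library under the control's name stays open: RPL4 had 21.1 reads per 1000 reads of the other ribosomal proteins in that column, against 10.7 to 19.4 in the guide libraries and 38.1 and 38.7 in the control libraries as analysed, a bound on the control side that was set after the value was seen. The column stood apart from both, with 21.3% of its reads in ribosomal proteins against 5.69% and 5.76% in the controls and 5.26% to 6.94% in the guide libraries, and its highest correlation, 0.913 with guide 1 replicate 3, was below the lowest between the libraries analysed when computed in the same way, 0.950. Relative to all reads, RPL4 stood at 4492 CPM in that column, above the control libraries as analysed (2168 and 2225). The guide libraries had 624 to 1197 CPM on that scale. RPL4 relative to ribosomal proteins and RPL4 relative to all reads thus point different ways and decide nothing. The control library that the authors discarded was not analysed here, so the column could not be set against it. Which column holds the library named cannot be told apart with these tables, and no biological explanation was tested.

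Longer genes had lower fold changes with both guides, with Spearman's rho across genes at -0.368 for guide 1 and -0.317 for guide 2, and between -0.426 and -0.227 in each of the 6 guide libraries against the control mean, while control replicate 2 against replicate 1 gave -0.0659. The trend stayed given expression (-0.341 and -0.291), whereas that with expression level, -0.153 and -0.137, shrank to -0.0306 and -0.0316 given length, which argues against abundance as the whole cause. A length shift between libraries without any RPL4 guide may be enough, since the deposited count column of control replicate 2 gave a rho of -0.47 against control replicate 1, though that column's origin is open. A separate handling of each group cannot be told apart from the guides, because the 3 numbers before the hyphen in the titles each belong to a single group and their meaning is not stated. The guides themselves stay among the open explanations.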

How the results depend on the processing

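The use of the deposited counts of control replicate 2 was chosen after seeing the data; the other alternatives were planned. For the counts of genes, the shared calls and RPL4, 76 alternative values stayed on their side of the threshold or within 1.5 times, 49 were weaker, 10 stronger and 0 reversed; for named genes these numbers were 3336, 239, 37 and 7, and for gene lists 404, 82, 12 and 6. The cause was not tested. Guide 1 against control (5437 genes) gave 3598 with unfiltered log2(FPKM + 1), 1479 with a 2-fold minimum and 2636 to 6315 leaving out a library. Guide 2 against guide 1 (3467) gave 1832, 541 and 1891 to 4655 in the same order. Guide 2 against control and the calls shared by the guides (7 each) gave 3 and 3 with library size alone, 34 and 33 with DESeq2, 0 and 0 with limma-voom (1226 genes of guide 2 at an unadjusted p under 0.05), 3 and 3 with log2(FPKM + 1), 4 and 3 with log2(FPKM + 0.1), 74 and 70 without a filter, 4 and 4 at a mean CPM of at least 5, 493 and 421 with the groups compared alone, and 0 to 206 and 0 to 198 leaving out a library, where edgeR gave 0 genes without control replicate 1, control replicate 2, guide 1 replicate 2 or guide 2 replicate 3, with 733, 788, 1083 and 1052 at an unadjusted p under 0.05. RPL4 with guide 2 lost its call at log2 fold changes of -0.89 with limma-voom (adjusted p = 0.132), -0.90 with unfiltered log2(FPKM + 1) (0.0528) and -0.88 at a mean CPM of at least 5 (0.0630), and ranged from -0.91 to -0.87 leaving out a library.

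Whether replicate numbers pair the libraries was left open. Same-numbered guide 1 and guide 2 libraries had correlations of their deviations of 0.007, 0.063 and 0.036, each the highest of its libraries. Control and guide 1 libraries of the same number had 0.063 and 0.038 by description and 0.063 and 0.030 by title. Control and guide 2 libraries had -0.180 and 0.230 by description and -0.180 and -0.348 by title. The title and description number control replicate 2 differently. With a replicate block by description and by title, guide 2 against control gave 4 and 3 genes, the shared calls 4 and 3, guide 1 against control 5059 and 4731, guide 2 against guide 1 3726 and 3044, and RPL4 with guide 2 -0.87 by title (adjusted p = 0.133). The block by description, the only one run on lists, ended the list calls of ribosomal proteins (adjusted p = 0.174 and 0.383 with guide 1 and guide 2), of the respiratory chain with guide 2 (0.0571) and of mitochondrial mRNAs with guide 1 (0.141) and no other list call; the immediate early list with guide 2, which had no call, had a median of -0.01.

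With the deposited counts of control replicate 2 the comparisons gave 187 (guide 1), 0 (guide 2) and 0 genes (guide 2 against guide 1) and 0 shared calls, with 4212, 2415 and 1878 genes at an unadjusted p under 0.05 in edgeR, the only tool run on these counts, and RPL4 with guide 2 at -2.09 (adjusted p = 0.330). Among results with a call in either setting, the reversed values all came from this alternative. With guide 1 they were -0.24 for ATP5H, -0.20 for CYCS, -0.16 for GADD45A, -0.84 for IFITM2, -0.57 for MRPL18, -0.15 for TIPIN and -0.42 for EBP. List medians reversed to -1.60 and -1.85 (guide 1 and guide 2) for ribosomal proteins, -1.01 and -1.47 for the respiratory chain and -0.60 and -1.18 for snoRNA hosts. At 10957278 to 14457832 reads per library and 2 control libraries, the test called 23.9% of genes changed 1.5-fold in simulations of guide 2 against control, so smaller effects of guide 2 may be missed. The simulations and the main fit both used a spread estimated over all groups, guide 1 included. Guide 2 against control gave 7 genes in the main fit and 493 with the groups compared alone. It gave 20, 0 and 206 without guide 1 replicate 1, 2 and 3. The guide 2 count thus also depends on the spread of the guide 1 libraries.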

Other observations

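The test of nuclear RNA with its lists, the test of the short exons of mitochondrial mRNAs with the rule on how well matched lists must fit, the account of gene types and noncoding RNAs, and the ranks among matched lists were chosen only after fold changes or library totals had been seen; the test of RNA cleavage outside mitochondria was chosen before.

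With guide 1, of 900 antisense genes 291 rose and 14 fell (median log2 fold change 0.72), of 713 long intergenic noncoding RNAs 230 rose and 26 fell (0.61), and of 133 sense intronic genes 39 rose and 1 fell (0.61). Protein-coding genes went 2043 up and 2452 down of 13270 (-0.04), and processed pseudogenes 65 up and 30 down of 566 (0.02). The median exon length was 1709.5 bases for antisense, 1679 for intergenic noncoding, 735 for sense intronic and 5173 for protein-coding genes, and no test compared the types at equal length. Because the strand setting is not given, reads of antisense genes and their partners cannot be told apart. With guide 2 the medians were 0.32 for antisense and 0.21 for intergenic noncoding genes, with 1 and 0 genes past the threshold, and in the direct test 183 and 147 of them were lower with guide 2 than with guide 1, against 7 and 10 higher.

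Among nuclear-retained noncoding RNAs, MIAT rose by 2.02 on the log2 scale with guide 1 (adjusted p = 0.00266), RN7SK, the RNA that holds the elongation factor P-TEFb, by 1.09 (adjusted p = 0.00338), NEAT1, the scaffold of paraspeckles, by 1.01 (adjusted p = 6.41e-05) and the imprinted antisense RNA KCNQ1OT1 by 0.72 (adjusted p = 0.0161). JPX fell by 0.39 (adjusted p = 0.0373), and MALAT1, at 0.75, did not pass (adjusted p = 0.0820). Among cytoplasmic noncoding RNAs SNHG8 rose by 1.44, DANCR by 1.18 and ZFAS1 by 1.10, and NORAD, a decoy of Pumilio proteins listed as LINC00657, fell by 0.50. SNHG8, DANCR and ZFAS1 are also members of the snoRNA host list, which rose with guide 1. The cytoplasmic list therefore cannot stand for cytoplasmic RNA in general. The median of 10 nuclear RNAs, 0.57, exceeded that of 10 cytoplasmic ones, 0.37, with a one-sided permutation p of 0.418 (100000 permutations). With snoRNA hosts in the cytoplasmic list this test cannot decide whether nuclear RNA fell less. That comparison does not take account of exon length, with medians of 10990 and 3075 bases, and among random protein-coding lists matched on length and expression the guide 1 medians ranked at percentile 100 and 88.9. Those random lists hold no noncoding genes, so the ranks can reflect gene type.

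Set against 10000 random lists matched on exon length and expression, the guide 2 median ranked at percentile 100 for histones and ribosomal proteins, 99.98 for snoRNA hosts, 99.96 for the respiratory chain, 98.2 for immediate early genes, 0.86 for interferon-stimulated genes and 0 for G2 and mitosis genes. S phase genes, glycolysis and ATF4 targets, which stood at the edges with guide 1, ranked at 35.7, 65.4 and 73.4 with guide 2. As with guide 1, genes matched on joined exons may differ in mRNA length, so these ranks cannot show a shift beyond it. The random lists again held protein-coding genes, so the rank of snoRNA hosts can reflect gene type.

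The median of the mitochondrially encoded mRNAs exceeded that of all genes by 0.458 on the log2 scale with guide 1, where 7 of 13 did not pass and the list was not called with an estimated correlation (adjusted p = 0.901), and by 0.0784 with guide 2, with a pooled SD between libraries of 0.239. If CasRx cut RNA outside mitochondria and spared RNA inside them, both values would exceed that spread. The guide 2 value is above 0 but within it. That SD pools all groups, and the guide 1 libraries were spread most. The 13 mRNAs stood above all genes by 9.38, 9.56 and 10.2 log2 CPM with guide 1. The values were 9.47, 9.42 and 9.39 with guide 2, and 9.35 and 9.31 in the control. The guide 2 libraries thus lay above both control libraries. A spread set mostly by guide 1 cannot decide the guide 2 value, so this stays open. Their short exons are another candidate explanation, and the guide 1 median ranked at percentile 85.2 of random nuclear lists. That comparison decides nothing, since the nearest nuclear genes were longer (1930 against 784 bases) and less abundant (9.63 against 13.4 log2 CPM). The call of this list with guide 1 was also lost without either control library (adjusted p = 0.0725 and 0.111) or any guide 2 library (0.0633 to 0.0700), and without guide 1 replicate 3 its median was 0.20.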
